A study of Mus musculus with 18 samples.

How the data were processed

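RNA was measured by sequencing in 18 libraries of 9 groups, 2 per group: mouse embryonic fibroblasts (D0), cells on days 2, 4, 6, 8, 10 and 12 of chemical reprogramming, induced pluripotent stem cells (riPSC) and R1 embryonic stem cells (mESC). Groups and replicate numbers were read from the sample titles. The labels give NovaSeq 6000 and 150 bp reads.

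Per the labels, the authors trimmed reads with fastp 0.20.1, aligned them to mm10 with HISAT2 2.2.1 and quantified them with StringTie 2.0. The deposited values, 1 file per library with 55401 Ensembl genes, are in FPKM. The labels do not state the unit of each column, and it was read from the values: column sums ranged from 561172 to 1696345, which excludes TPM, and in single-exon genes value times length fell in steps of 1 read or read pair. That step also gave the estimate of depth, 16.5 to 61.35 M read pairs per library, from 8956 single-exon genes. The annotation release is not stated. Symbols, coordinates and exonic lengths came from a mouse annotation of GRCm38 (mm10), in which 55141 identifiers had a symbol.

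Values as deposited were transformed to log2(FPKM + 1), and 16439 genes with an FPKM of at least 1 in at least 2 libraries were tested. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 18 libraries (9 residual degrees of freedom), with eBayes without a trend. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05 and a fold difference of at least 2 on that scale, and "rose", "fell", "higher" and "lower" of a gene refer to such calls. The comparisons were each day with D0, each day with the one before, riPSC with D0, D12 with riPSC and riPSC with mESC. A gene counted as transient if it was called in 1 direction against both D0 and riPSC on the same day. Tools for counts were not used, since the files hold none.

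The 35 gene lists were fixed before the data were examined. They cover fibroblast matrix, mesenchymal transcription factors, epithelium, naive and formative pluripotency, extraembryonic endoderm, the 2-cell-like state, trophoblast, germline, cell cycle, cyclin-dependent kinase inhibitors, p53 targets, ribosome biogenesis, Myc family, negative regulators of mTORC1, autophagy and lysosome, fatty acid oxidation, glycolysis, cholesterol synthesis, AP-1 and immediate early genes, TGF-beta, Wnt targets, DNA methylation, heterochromatin, interferon, imprinted genes, sex-linked genes, ribosomal proteins, oxidative phosphorylation, and markers of neural, myeloid, endothelial, muscle, adipocyte and stratified epithelial cells. Each list was tested with camera of limma at a preset correlation of 0.01 in 9 comparisons, and p-values were adjusted over all 315 tests, 113 of which passed; not each of them is described. With an estimated correlation 6 passed: myeloid and muscle markers at D2 against D0, epithelial genes at D8 against D6, 2-cell-like genes at D12 against D10, and myeloid markers in riPSC against D0 and against mESC. The count of called members adjusted over the list alone is given where it differed from that over all genes, which it did in 7 of the 315 tests.

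Genes were named by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest called log2 fold changes with a mean of at least 10 in riPSC against D0, D12 against riPSC and riPSC against mESC, and 5 and 5 in each 2-day step. It also takes the 10 strongest transient genes per direction, up to 4 called members of each list described and any member given as not called, and in every comparison a fixed set: Pou5f1, Nanog, Sox2, Klf4, Esrrb, Zfp42, Dppa2, Dppa4, Lin28a, Sall4, Cdh1, Epcam, Col1a1, Thy1, Twist1, Zeb2, Gata4, Sox17, Zscan4c, Myc, Cdkn1a and Xist. Not every gene the rule takes is printed, the fixed set included. No fold is given against a group in which both libraries were listed at 0.

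The procedure was tested on simulated data. Of 50 genes changed between riPSC and D0 by a simulated log2 fold of 1, 36% were recovered, and of 50 at each of 2, 3 and 4, 98%, 96% and 98%. In 20 simulations without any change, at most 2 genes were called in any of 14 comparisons. The simulated noise was normal, with 1 spread per gene shared by all groups, as the model assumes. It does not show the error rate where replicates differed more, as in D0, D2 and D4.

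Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter of 5, median-of-ratios scaling, quantile normalization, eBayes with a trend, a fit of only the libraries compared, the replicate number as a block, no fold threshold, leaving out each replicate, and, for lists, an estimated correlation and fry. Added after the data were examined were removal of the length trend (a lowess of each library's deviation from the mean of all libraries over log2 exonic length, subtracted), group variance weights, and a fit without the D0, D2 and D4 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.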

Results

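The series followed mouse embryonic fibroblasts through a chemical reprogramming course by RNA sequencing, with reprogrammed and embryonic stem cells as end points. The fibroblasts (D0) came from E13.5 embryos of a 129 by OG2 cross. Cells were sampled on days 2, 4, 6, 8, 10 and 12 (D2 to D12), and the course was compared with induced pluripotent stem cells (riPSC) and the R1 embryonic stem cell line (mESC). Each of the 9 groups held 2 libraries, 18 in all, and nothing in the labels says whether the 2 came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The deposited values were FPKM, fragments per kilobase of transcript scaled to the mapped fragments of each library, for 55401 Ensembl genes. Depth was not given, and it was estimated from the value of 1 read in single-exon genes: 16.5 to 24.6 M read pairs in 17 libraries and 61.3 M in D2 replicate 2. Of 16439 genes tested, the median absolute difference between replicates on the log2(FPKM + 1) scale was 0.28 in D0, 0.243 in D2 and 0.184 in D4, against 0.09 to 0.141 in the later groups and stem cells. Levels below are mean FPKM ± SD of n = 2 libraries, or both libraries' values where either was listed at 0. Such a 0 may be a failed estimate or a true absence, and which was not tested. Nnt, a mitochondrial enzyme gene used by most cells, was listed at 0 in both D0 and both mESC libraries. Fold changes are on the log2(FPKM + 1) scale with their standard errors, which understates changes of low genes.

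The libraries also differed in make-up. Mitochondrial transcripts took 0.437% and 1.89% of the FPKM sum in the D0 libraries, 34.1% and 15.9% in D2, 62.3% and 62.1% in D12 and 28.1% and 27.0% in riPSC. Genes for ribosomal proteins took 33.0% and 27.5% of the sum in D0 and 2.74% and 2.93% in D12. An FPKM sum gives short transcripts more weight. With FPKM weighted by exonic length, mitochondrial transcripts took 0.115% and 0.275% in D0 and 5.94% and 2.29% in D2. They took 18.6% and 18.2% in D12 and 4.18% and 3.91% in riPSC. Ribosomal protein genes then took 26.9% and 21.1% in D0 and 4.72% and 4.95% in D12. In each library this mitochondrial share was lower than that of the FPKM sum, the one given below unless stated. Against D0, coding genes with over 8000 bases of annotated exon had a median log2 fold change of 1.30 at D12 and those of 1000 to 2000 bases one of 0.00. The 2 D0 libraries differed in the same property, by -0.256 for the longest class. The labels do not say whether the D0 libraries were prepared like the others or how intact their RNA was, so a comparison with D0 can hold such a difference as well as one between cells. Comparisons with D0 carry this length trend, and their counts of changed genes below are given with it and with it removed.

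The first question was how far each day lay from the fibroblasts and from the pluripotent cells. Across genes, the mean correlation with the riPSC libraries was 0.720 for D0, 0.735 for D2, 0.739 for D4 and 0.716 for D6, then 0.798 for D8, 0.815 for D10 and 0.775 for D12. It was 0.974 between riPSC and mESC. Genes are not independent replicates, and these coefficients carry no test. The first principal component held 44.7% of the variance, the second 26.3% and the third 11.2%.

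**Figure D1:**
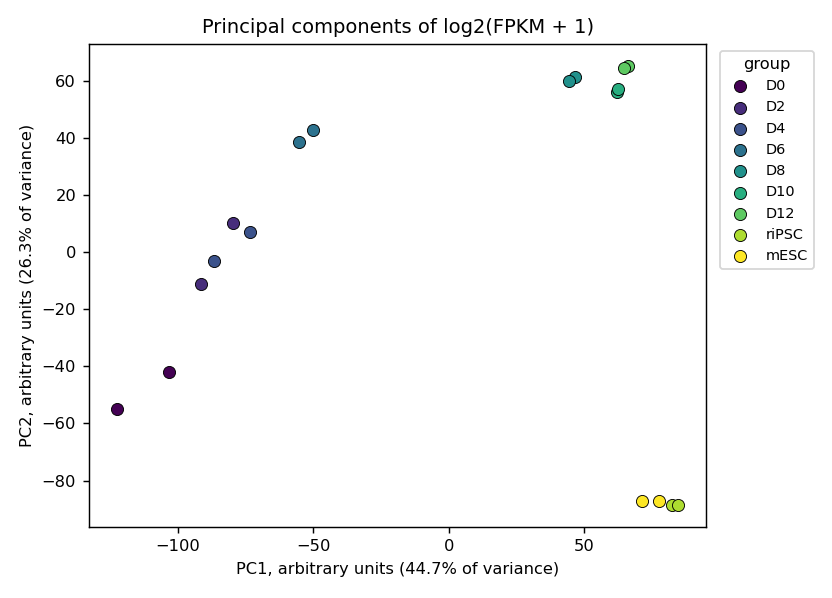
Principal components 1 (44.7% of variance) and 2 (26.3%) of log2(FPKM + 1) over 16439 genes; each point is 1 of 18 libraries, coloured by group. D8, D10 and D12 lie on the side of the stem cells on component 1 and apart from them on component 2.

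Compared with D0, 3965 genes changed at D2, 4319 at D4, 6840 at D6, 8607 at D8, 8561 at D10, 8507 at D12 and 8729 in riPSC (limma, adjusted p under 0.05 and at least a 2-fold difference). Of those, 3204, 3531, 5395, 6669, 6423, 6246 and 6595 were higher than in D0. The split between higher and lower depended on scaling. With median-of-ratios scaling the higher genes numbered 2438, 2148, 3769, 4936, 4916, 5133 and 4804 and the lower ones 1542, 1774, 2690, 3247, 3357, 3327 and 3461. With the length trend removed, 1672, 1610, 2660, 3392, 3463, 3750 and 3682 were higher and 1319, 1520, 2566, 3285, 3524, 3531 and 3803 lower. The median log2 fold change of all genes against D0 was 0.24 at D2 and 0.68 at D8, and 0.05 and 0.32 after median-of-ratios scaling. Changes against D0 are therefore to be read relative to that shift. When only the 4 libraries compared entered the fit, the D2 count was 88 and the D4 count 1792. Replicates differed more in D0, D2 and D4 than in the other groups, and all share 1 estimate of spread. P-values of comparisons among D0, D2 and D4 may therefore be too small.

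Between neighbouring days, the number of changed genes was 1667 from D2 to D4, 3037 from D4 to D6, 4348 from D6 to D8, 470 from D8 to D10 and 1757 from D10 to D12. The step from D2 to D4 had 930 higher and 737 lower genes, or 728 and 939 with median-of-ratios scaling. When only its 4 libraries entered the fit, its count was 337. The step from D4 to D6 had 1910 higher and 1127 lower, with the length trend removed 1541 and 1262, and with quantile normalization 1439 and 1291. The step from D6 to D8 had 2486 higher and 1862 lower, and the majority turned to 2027 higher and 2175 lower with the length trend removed and to 2107 and 2250 with quantile normalization. Of the 470 genes at D10, 400 fell. The step to D12 had 988 higher and 769 lower genes, or 1111 and 580 with median-of-ratios scaling. The majority turned to 1357 higher and 1364 lower with a pseudocount of 0.1 and to 2720 and 3102 with no fold threshold.

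**Figure D2:**
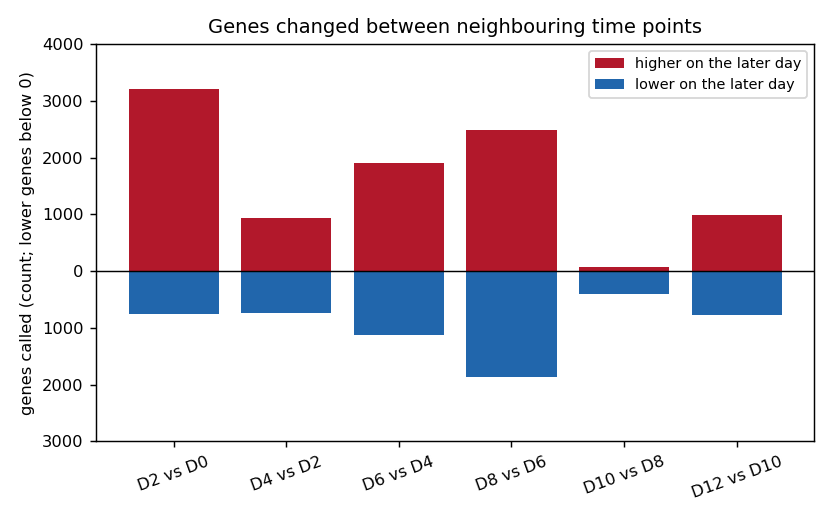
Genes called higher (above the line) or lower (below it) in each comparison of neighbouring time points, with limma on FPKM as deposited (adjusted p under 0.05, at least 2-fold). The bars are counts of genes; the step from D6 to D8 has 4348 and the step from D8 to D10 has 470. With other scalings the majority turns in the steps from D2 to D4 and from D6 to D8, and the excess of higher genes from D0 to D2 shrinks.

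By D2, Ccn2, Acta2 and Eln had fallen and 12 of 15 Wnt target genes had risen. Among TGF-beta ligands, receptors and targets, 5 of 15 rose and 7 fell, and the list was not called (camera adjusted p = 0.1055). The matricellular gene Ccn2 fell from 251 ± 72.5 in D0 to 1.08 ± 0.985 (log2 fold change -6.97 ± 0.26, limma adjusted p = 1.85e-09), and the smooth muscle actin gene Acta2 was at 2330.0 ± 494 in D0 and 142 ± 152 in D2 (log2 fold change -4.61 ± 0.59, limma adjusted p = 5.41e-05). Eln, which encodes elastin, went from 126 ± 38.0 to 2.91 ± 0.319 (log2 fold change -5.00 ± 0.18, limma adjusted p = 1.27e-09). Among Wnt/beta-catenin target genes, 12 of 15 rose (camera adjusted p = 5.90e-06, adjusted p = 0.483 with an estimated correlation). Notum, a secreted Wnt inhibitor, rose from 0.498 ± 0.0929 to 144 ± 68.3 (log2 fold change 6.52 ± 0.24, limma adjusted p = 1.84e-09), and Axin2 and Nkd1, negative feedback genes of the same pathway, reached 32.3 ± 18.8 and 94.1 ± 61.9. The retinol transporter gene Stra6 was at 171 ± 63.1 in D2 and 0 and 0.150 in D0, and the metallothionein gene Mt3 at 304 ± 11.9 and 2.60 ± 1.38. Among mesenchymal transcription factors, 8 of 12 rose and 1 fell (camera adjusted p = 0.0497, adjusted p = 0.704 with an estimated correlation), and the camera adjusted p was 0.12 with a pseudocount of 0.1. Twist1 rose from 21.9 ± 10.7 to 359.7 ± 131 (log2 fold change 4.01 ± 0.28, limma adjusted p = 4.40e-07) and stayed at 429.7 ± 0.531 at D6.

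In the same interval 9 of 9 muscle and 10 of 13 myeloid markers fell. Of endothelial markers 3 of 9 rose, and that list was not called (camera adjusted p = 0.592). Among striated muscle genes, 9 of 9 fell (camera adjusted p = 9.41e-13, adjusted p = 0.0375 with an estimated correlation). The troponin gene Tnnt2 went from 57.1 ± 16.6 to 0.430 ± 0.373 (log2 fold change -5.34 ± 0.21, limma adjusted p = 2.96e-09). Among myeloid genes, 10 of 13 fell (camera adjusted p = 9.41e-13, adjusted p = 0.00620 with an estimated correlation), and the complement genes C1qa and C1qb were at 34.6 ± 8.603 and 25.04 ± 1.57 in D0 and at 0.283 ± 0.194 and 1.63 ± 0.492 in D2. Among fibroblast matrix genes, 7 of 25 rose and 10 fell (camera adjusted p = 0.00613, adjusted p = 0.707 with an estimated correlation); Tagln, a contractile gene, fell to 100.3 ± 101 while Pdgfra, a growth factor receptor, rose from 2.54 ± 0.502 to 82.0 ± 33.1. Among interferon-stimulated genes, 1 of 17 rose and 4 fell (camera adjusted p = 0.00243, adjusted p = 0.321 with an estimated correlation). The lists of adipocyte and neural markers were also called, with 1 of 4 adipocyte genes lower and 3 of 7 neural genes higher, at camera adjusted p = 0.0102 and 0.0473 (adjusted p = 0.249 and 0.511 with an estimated correlation). With the length trend removed those adjusted p-values were 0.066 and 0.054. The neural list was also not called with the replicate block or with a pseudocount of 0.1, at adjusted p = 0.053 in both.

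From D2 to D4, 7 of 16 extraembryonic endoderm and 9 of 18 imprinted genes rose, and neither list call held with an estimated correlation (adjusted p = 0.249 and 0.642). Mitochondrial transcripts took 34.1% and 15.9% of the FPKM sum in the D2 libraries and 6.42% and 12.4% in D4. On the first 3 principal components each D2 library lay nearer to a D4 library than to the other D2 library. D2 replicate 1 (-79.5, 10.3, -38.6) lay by D4 replicate 2 (-73.4, 7.2, -35.8). D2 replicate 2 (-91.3, -11.2, -9.3) lay by D4 replicate 1 (-86.7, -3, -18.5). The camera adjusted p of the endoderm list was 1.24e-04. Sox17, a transcription factor of endoderm, rose from 0.613 ± 0.525 to 38.2 ± 10.9 (log2 fold change 4.61 ± 0.23, limma adjusted p = 5.91e-08), and Cited1 from 15.6 ± 1.93 to 169 ± 18.9. S100g, a calcium-binding protein gene, went from 0.558 ± 0.135 to 175 ± 14.4 and the water channel gene Aqp8 from 0.188 ± 0.0814 to 24.8 ± 0.128. The camera adjusted p of the imprinted list was 0.00494. H19 rose from 1517 ± 279 to 6322 ± 804 (log2 fold change 2.06 ± 0.20, limma adjusted p = 9.91e-06) and Mest from 24.7 ± 15.9 to 115 ± 16.7. Of myeloid markers 2 of 13 fell and of muscle markers 2 of 9 (camera adjusted p = 0.00544 and 0.00575, adjusted p = 0.158 and 0.376 with an estimated correlation). The calcium-binding protein gene S100a4 fell from 1027 ± 22.4 to 47.4 ± 16.8 (log2 fold change -4.45 ± 0.22, limma adjusted p = 6.14e-08).

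At D6, 13 of 17 p53 target, 11 of 13 AP-1 and immediate early and 11 of 25 fibroblast matrix genes rose, and 23 of 27 cell cycle genes fell. With an estimated correlation none of these 4 list calls held (adjusted p = 0.406, 0.200, 0.686 and 0.327). Mitochondrial transcripts took 6.42% and 12.4% of the FPKM sum in the D4 libraries and 44.2% and 35.4% in D6, beside each list of this step. With FPKM weighted by length they took 0.951% and 1.75% in D4 and 8.17% and 5.82% in D6. The camera adjusted p of the p53 list was 1.59e-06. Mdm2, which encodes the ubiquitin ligase of p53, rose from 21.9 ± 2.58 to 235 ± 9.41 (log2 fold change 3.36 ± 0.25, limma adjusted p = 6.81e-07), and the cyclin-dependent kinase inhibitor gene Cdkn1a from 107 ± 17.2 to 387 ± 0.0939 (log2 fold change 1.86 ± 0.24, limma adjusted p = 6.24e-05). The camera adjusted p of the AP-1 list was 1.65e-05, with Junb at 43.5 ± 8.27 in D4 and 479 ± 2.82 in D6. The chemokine gene Ccl2 rose from 2.71 ± 1.03 to 316 ± 14.8 (log2 fold change 6.44 ± 0.29, limma adjusted p = 1.83e-08), Cxcl1 from 1.86 ± 0.126 to 107 ± 4.81, and the adhesion gene Icam1 from 1.26 ± 0.393 to 67.0 ± 1.30. By D8, Ccl2 was back at 15.4 ± 0.737 (log2 fold change -4.27 ± 0.29, limma adjusted p = 1.18e-07). The camera adjusted p of the cell cycle list was 8.45e-14. The survivin gene Birc5 fell from 117 ± 8.55 to 19.4 ± 0.554 and the mitotic kinase gene Aurka from 30.6 ± 1.81 to 6.55 ± 0.520. The camera adjusted p of the fibroblast matrix list was 0.00321. Among Wnt targets, 1 of 15 rose and 9 fell (camera adjusted p = 0.00127, adjusted p = 0.642 with an estimated correlation), Dkk1 going from 26.4 ± 2.98 to 0.798 ± 0.0897. Among epithelial genes, 9 of 19 rose (camera adjusted p = 4.81e-05, adjusted p = 0.172 with an estimated correlation). Among nucleolar ribosome biogenesis factors, 7 of 20 fell (camera adjusted p = 5.48e-06, adjusted p = 0.498 with an estimated correlation).

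From D6 to D8, 17 of 19 epithelial, 14 of 16 extraembryonic endoderm and 19 of 30 pluripotency genes rose, and of these list calls the epithelial one held with an estimated correlation. Mitochondrial transcripts took 50.2% and 52.4% of the FPKM sum in D8. Among epithelial genes, 17 of 19 rose (camera adjusted p = 3.36e-12, adjusted p = 0.0375 with an estimated correlation). E-cadherin, encoded by Cdh1, rose from 2.02 ± 0.126 to 99.6 ± 6.65 (log2 fold change 5.06 ± 0.10, limma adjusted p = 4.69e-12) and Epcam from 11.7 ± 0.0269 to 267 ± 1.27 (log2 fold change 4.40 ± 0.11, limma adjusted p = 2.45e-11). Among extraembryonic endoderm genes, 14 of 16 rose (camera adjusted p = 3.55e-08, adjusted p = 0.110 with an estimated correlation). Gata4, a gene on chromosome 14 from 63198922 to 63271692 in mm10 (ENSMUSG00000021944), rose from 4.91 ± 0.346 to 113 ± 0.753 (log2 fold change 4.27 ± 0.12, limma adjusted p = 5.58e-11), Sox17 reached 124 ± 1.59, and Lama1, a basement membrane laminin gene, 153 ± 15.3. Among pluripotency genes, 19 of 30 rose (camera adjusted p = 2.65e-09, adjusted p = 0.200 with an estimated correlation). Pou5f1, a gene on chromosome 17 from 35506018 to 35510772 in mm10 (ENSMUSG00000024406), was listed at 0.0576 and 0 in D6 and 45.1 ± 0.335 in D8 (log2 fold change 5.49 ± 0.09, limma adjusted p = 1.91e-12). Dppa5a reached 172 ± 0.766 and Tdgf1 51.9 ± 1.28, while Nanog stood at 0.263 ± 0.0646 and Sox2 at 4.30 ± 0.383 and neither was called.

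Among cell cycle genes in the same step, 23 of 27 rose (camera adjusted p = 6.12e-08, adjusted p = 0.498 with an estimated correlation). Among fibroblast matrix genes, 21 of 25 fell (camera adjusted p = 2.50e-09, adjusted p = 0.346 with an estimated correlation); Thy1, a fibroblast surface gene, fell from 889 ± 6.43 to 125 ± 2.55 (log2 fold change -2.82 ± 0.15, limma adjusted p = 1.21e-08). Among mesenchymal transcription factors, 1 of 12 rose and 9 fell (camera adjusted p = 3.85e-05, adjusted p = 0.375 with an estimated correlation), and Twist1 fell to 35.4 ± 1.014. Of the cyclin-dependent kinase inhibitors, 1 of 7 rose and 5 fell (camera adjusted p = 0.00632, adjusted p = 0.434 with an estimated correlation); Cdkn2a went from 157 ± 13.1 to 32.5 ± 0.897. Among p53 targets, 8 of 17 fell (camera adjusted p = 2.86e-04, adjusted p = 0.511 with an estimated correlation). Lists of markers of other lineages were called as well. Among trophoblast genes, 6 of 11 rose and 1 fell (camera adjusted p = 0.00590, adjusted p = 0.164 with an estimated correlation), with Cdx2, a trophectoderm regulator, at 20.1 ± 1.12. Among stratified epithelium genes, 7 of 8 rose (camera adjusted p = 7.12e-04, adjusted p = 0.110 with an estimated correlation). Among endothelial genes, 6 of 9 rose (camera adjusted p = 0.00667, adjusted p = 0.302 with an estimated correlation), Cdh5 reaching 14.8 ± 0.605.

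**Figure D3:**
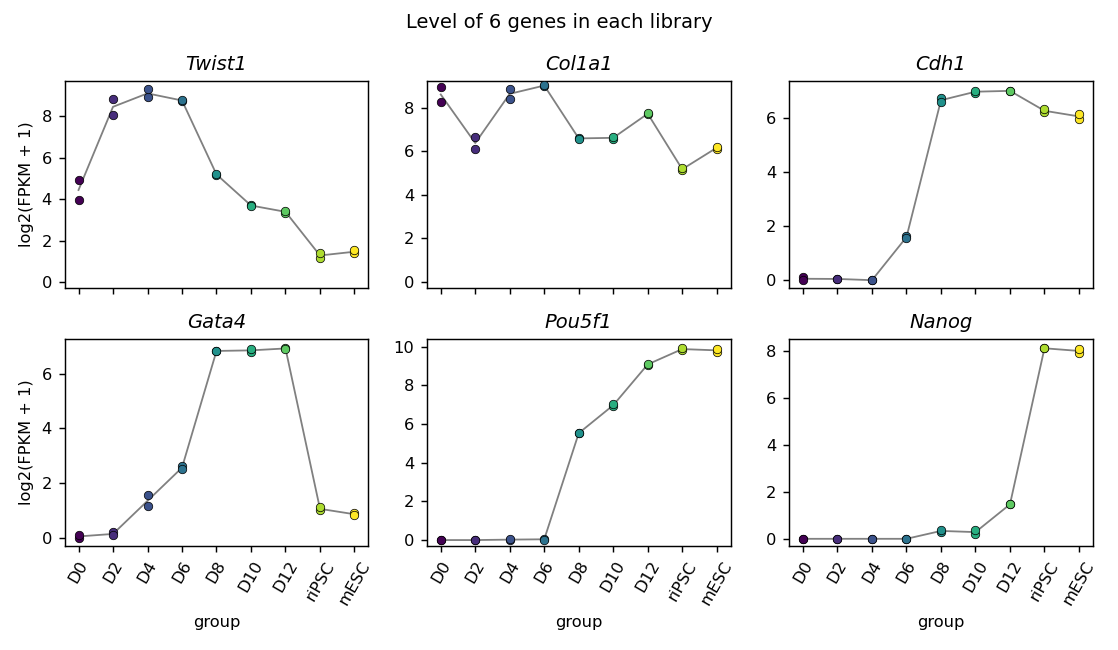
Level of 6 genes in each of the 18 libraries, as log2(FPKM + 1), by group in course order; points are libraries and lines join group means. Twist1 is high from D2 to D6, Cdh1 and Pou5f1 are high from D8 on, Gata4 is high from D8 to D12 and low in riPSC and mESC, and Nanog is high in riPSC and mESC.

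From D8 to D10, 470 genes changed. Pou5f1 rose to 125 ± 4.92 (log2 fold change 1.45 ± 0.09, limma adjusted p = 1.50e-06), the folate receptor gene Folr1 from 16.9 ± 0.0576 to 48.1 ± 3.45 (log2 fold change 1.46 ± 0.16, limma adjusted p = 1.05e-04), and Lrpap1 from 51.6 ± 0.402 to 145 ± 9.98. Among pluripotency genes, 3 of 30 rose (3 and 1 adjusted over the list alone, camera adjusted p = 4.14e-05, adjusted p = 0.406 with an estimated correlation). Among AP-1 and immediate early genes, 8 of 13 fell (0 and 9 adjusted over the list alone, camera adjusted p = 3.85e-12, adjusted p = 0.0531 with an estimated correlation); Atf3 fell from 32.9 ± 2.34 to 9.49 ± 1.39 (log2 fold change -1.70 ± 0.24, limma adjusted p = 6.50e-04), and did not pass with a pseudocount of 0.1, at adjusted p = 0.22 in limma. Among fibroblast matrix genes, 9 of 25 fell (0 and 10 adjusted over the list alone, camera adjusted p = 2.41e-05, adjusted p = 0.511 with an estimated correlation). The trophoblast, stratified epithelium and endothelial lists were called lower, with 2 of 11, 1 of 8 and 0 of 9 members called (camera adjusted p = 3.37e-04, 0.00350 and 0.00239). Their adjusted p-values were 0.110, 0.159 and 0.249 with an estimated correlation. The protease gene Mmp3 fell from 23.2 ± 0.0147 to 2.58 ± 0.0795 and the angiotensin receptor gene Agtr2 from 32.2 ± 0.235 to 2.11 ± 0.460.

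At D12, 11 of 11 tested 2-cell-like and 14 of 30 pluripotency genes rose, and 12 of 17 interferon-stimulated, 9 of 15 Wnt target and 14 of 27 cell cycle genes fell. Of these list calls the 2-cell-like one held with an estimated correlation. Mitochondrial transcripts took 52.3% and 51.4% of the FPKM sum in D10 and 62.3% and 62.1% in D12. With FPKM weighted by length they took 11.7% and 11.1% in D10 and 18.6% and 18.2% in D12. Of the 2-cell-like list, 11 of 11 rose (camera adjusted p = 4.93e-15, adjusted p = 0.0375 with an estimated correlation). Zscan4f was at 0 and 0.0259 in D10 and 12.03 ± 0.446 in D12 (log2 fold change 3.69 ± 0.11, limma adjusted p = 2.30e-10), and Zscan4c, listed at 0 in both D10 libraries, reached 6.23 ± 0.04998 (limma adjusted p = 5.79e-10). The 11 are those of 22 listed genes that passed the filter on low values, and only 2 of them pass it without the D12 libraries, so the filter favours a rise. Members of this family are near-identical copies that share reads, so their single levels are uncertain. Dppa1, Zg16 and Havcr1, each under 1 in D10, reached 69.0 ± 8.45, 75.2 ± 3.58 and 68.2 ± 2.99 (log2 fold change 5.42 ± 0.09, limma adjusted p = 1.32e-12 for Havcr1). Among pluripotency genes, 14 of 30 rose and 2 fell (camera adjusted p = 1.59e-06, adjusted p = 0.291 with an estimated correlation). Pou5f1 rose to 543 ± 21.1 (log2 fold change 2.11 ± 0.09, limma adjusted p = 4.43e-09), Dppa3 from 0.407 ± 0.182 to 30.03 ± 1.83 and Zfp42 from 3.08 ± 0.123 to 22.2 ± 2.03. Xist, the RNA that coats the inactive X chromosome, rose from 4.18 ± 0.174 to 63.8 ± 2.71 (log2 fold change 3.65 ± 0.11, limma adjusted p = 2.81e-10). In the same step 3 of the 4 Y-linked genes measured had log2 ratios of FPKM between -0.86 and -1.23 and Eif2s3y had one of -0.10, and none of the 4 was called.

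Among interferon-stimulated genes, 12 of 17 fell (camera adjusted p = 7.65e-08, adjusted p = 0.110 with an estimated correlation); Oasl2 fell from 34.8 ± 2.51 to 5.52 ± 1.42 (log2 fold change -2.47 ± 0.24, limma adjusted p = 7.36e-06). Among Wnt targets, 1 of 15 rose and 9 fell (camera adjusted p = 0.00128, adjusted p = 0.642 with an estimated correlation), and Notum fell to 2.095 ± 0.111 (log2 fold change -3.58 ± 0.24, limma adjusted p = 2.33e-07). Among cell cycle genes, 14 of 27 fell (camera adjusted p = 3.87e-08, adjusted p = 0.498 with an estimated correlation); Cdk1 fell from 21.4 ± 1.71 to 5.95 ± 0.988 (log2 fold change -1.69 ± 0.19, limma adjusted p = 2.06e-05). Myc, a growth regulator, fell from 18.5 ± 0.0760 to 2.03 ± 0.312 (log2 fold change -2.69 ± 0.21, limma adjusted p = 1.18e-06). Among glycolysis genes, 3 of 15 fell (camera adjusted p = 0.00726, adjusted p = 0.511 with an estimated correlation), with Pkm at 287 ± 18.2 and 102 ± 1.43. Among germline genes, 4 of 14 rose (camera adjusted p = 6.17e-04, adjusted p = 0.249 with an estimated correlation), Dazl rising from 1.19 ± 0.267 to 16.8 ± 3.14. Gata4 and Sox17 stayed high, at 120.4 ± 1.58 and 106 ± 20.2, and neither was called in this step.

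**Figure D4:**
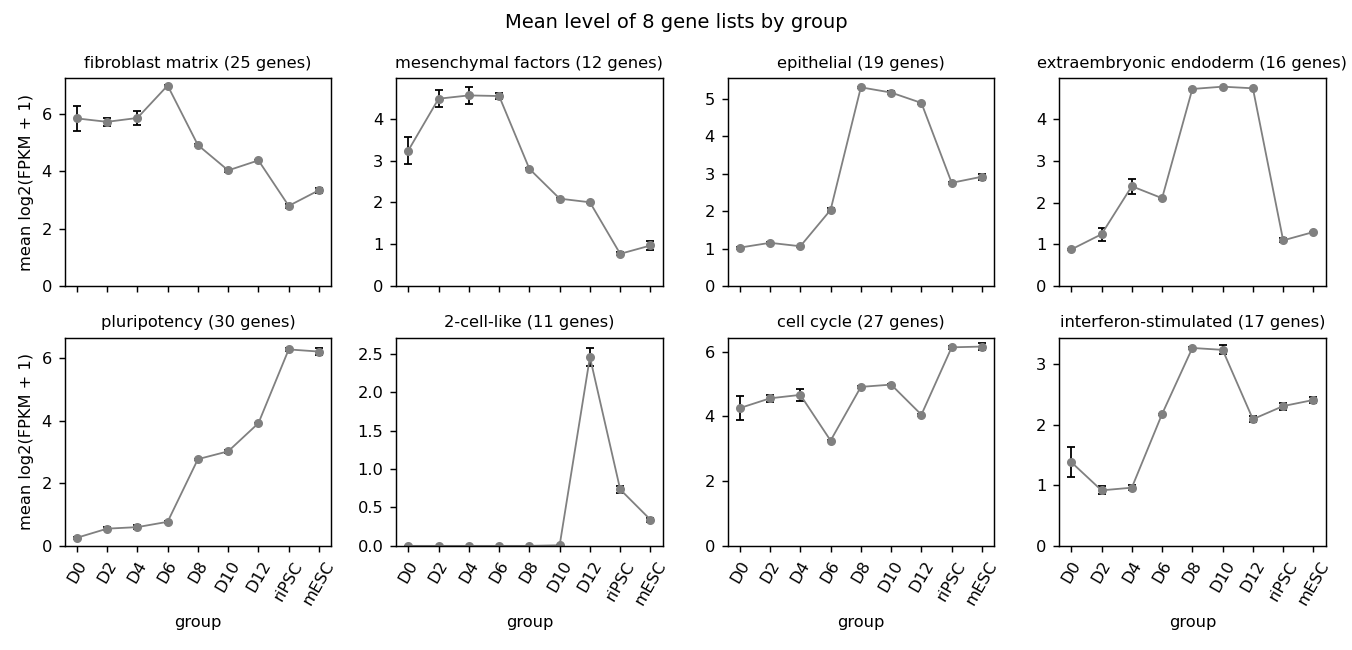
Mean log2(FPKM + 1) over the members of 8 gene lists, by group in course order; points are means and bars the SD of n = 2 libraries. The cell cycle list dips at D6 and at D12, the epithelial and extraembryonic endoderm lists rise at D8, and the pluripotency list is highest in riPSC and mESC.

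Genes that were higher on at least 1 day than in both D0 and riPSC numbered 4369, and 1172 were lower than in both. They numbered 4018 and 1496 with median-of-ratios scaling, and 3581 and 1668 with the length trend removed. On D12 alone 2015 genes were higher than in both, where independent lists would share 1043.7, and 709 were lower, against 447.4. On D2 and D4 the genes lower than in both numbered 186 and 150, fewer than the 213.2 and 207 of independent lists. Simulated unchanged groups gave 0 in either direction. They do not gauge the overlap to be met where D0, the days and riPSC all differ. The 2 comparisons of a day share its libraries, so the overlap is not free of them. D12 was the last day sampled, so no return within the course was seen for genes extreme there. riPSC were grown on feeder cells with LIF, CHIR99021 and PD0325901, and amounts of these are recorded for riPSC and mESC only. A difference of a day from riPSC can therefore hold one of culture. The genes with the largest transient rises included S100g, at 3763 ± 86.1 on D8, Aqp8, at 498 ± 6.62 on D12, and Cyp26a1, a retinoic acid catabolic enzyme gene, at 218 ± 0.261 on D12. Those with the largest transient falls included Igfbp2, at 6.51 ± 0.149 on D12 against 235 ± 5.89 in D0 and 509.8 ± 33.2 in riPSC. The serine synthesis gene Phgdh and the folate cycle gene Mthfd2 were also among the 10 largest falls, at 11.1 ± 0.448 on D12 and 3.76 ± 0.0415 on D10 against 152 ± 12.9 and 75.2 ± 3.71 in riPSC.

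In riPSC compared with D0, 8729 genes changed. Among pluripotency genes, 30 of 30 were higher (camera adjusted p = 1.31e-12, adjusted p = 0.132 with an estimated correlation). Dppa5a rose from 0 and 0.0663 to 2510.0 ± 143 (log2 fold change 11.25 ± 0.13, limma adjusted p = 1.82e-14); Pou5f1, Nanog and Tdgf1 were listed at 0 in both D0 libraries and reached 939.9 ± 41.9, 274 ± 1.58 and 575 ± 10.6. Nanog lies on chromosome 6, 122707489 to 122714633 in mm10. Among fibroblast matrix genes, 2 of 25 were higher and 22 were lower (camera adjusted p = 5.85e-12, adjusted p = 0.269 with an estimated correlation), Acta2 going from 2330.0 ± 494 to 3.63 ± 0.567 (log2 fold change -8.96 ± 0.59, limma adjusted p = 2.95e-08). The imprinted genes H19 and Igf2 fell from 2159 ± 769 and 299 ± 128 to 7.27 ± 0.145 and 0.623 ± 0.0926 (log2 fold change -7.98 ± 0.20, limma adjusted p = 4.37e-12 for H19). Among TGF-beta ligands, receptors and targets, 3 of 15 were higher and 12 were lower (camera adjusted p = 2.41e-05, adjusted p = 0.287 with an estimated correlation). Among genes for DNA methylation and for its removal, 8 of 9 were higher (camera adjusted p = 0.00955, adjusted p = 0.511 with an estimated correlation). Tet1, a gene for its removal, was at 0 and 0.0320 in D0 and 15.8 ± 1.45 in riPSC. Among heterochromatin regulators, 16 of 19 were higher (camera adjusted p = 0.00749, adjusted p = 0.686 with an estimated correlation). Among germline genes, 12 of 14 were higher (camera adjusted p = 5.08e-04, adjusted p = 0.249 with an estimated correlation). Of myeloid markers, 2 of 13 were higher and 10 were lower (camera adjusted p = 1.65e-05, adjusted p = 0.0375 with an estimated correlation), and of muscle markers, 1 of 9 was higher and 8 were lower (camera adjusted p = 1.61e-06, adjusted p = 0.124 with an estimated correlation). The D0 libraries held 0.437% and 1.89% mitochondrial transcripts and riPSC 28.1% and 27.0%, beside each of these lists.

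D12 cells differed from riPSC in 6000 genes, 2747 higher and 3253 lower as deposited and 3111 and 2592 with median-of-ratios scaling, or 3091 and 2789 with the length trend removed. These differences can hold one of culture, since the feeder cells and medium given for riPSC are not recorded for D12. Among pluripotency genes, 23 of 30 were lower (camera adjusted p = 2.59e-08, adjusted p = 0.239 with an estimated correlation). Nanog was at 1.76 ± 0.000314 at D12 and 274 ± 1.58 in riPSC (log2 fold change -6.64 ± 0.09, limma adjusted p = 3.79e-14), Sox2 at 3.83 ± 0.0464 and 246 ± 16.1 (log2 fold change -5.67 ± 0.19, limma adjusted p = 6.66e-11), and Fgf4 was listed at 0 in both D12 libraries against 105 ± 0.627. Pou5f1 and Dppa3 were among the 7 members that were not called, at 543 ± 21.1 and 30.03 ± 1.83 on D12. Among extraembryonic endoderm genes, 14 of 16 were higher and 1 was lower (camera adjusted p = 1.41e-07, adjusted p = 0.124 with an estimated correlation), with Gata4 at 1.08 ± 0.113 and Sox17 at 0.446 ± 0.228 in riPSC. The basement membrane collagen gene Col4a1 was at 1057 ± 19.8 on D12 and 5.21 ± 0.110 in riPSC (log2 fold change 7.41 ± 0.17, limma adjusted p = 2.58e-12). Of epithelial genes, 14 of 19 were higher and 1 was lower (camera adjusted p = 4.64e-07, adjusted p = 0.110 with an estimated correlation). Of trophoblast genes, 7 of 11 were higher and 1 was lower (camera adjusted p = 0.00504, adjusted p = 0.161 with an estimated correlation). Of fibroblast matrix genes, 16 of 25 were higher and 5 were lower (camera adjusted p = 7.44e-04, adjusted p = 0.642 with an estimated correlation). Of the 2-cell-like list, 10 of 11 were higher (camera adjusted p = 9.93e-07, adjusted p = 0.164 with an estimated correlation). Only 2 of those 11 pass the filter on low values without the D12 libraries, so the filter favours this result too.

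Among cell cycle genes, 24 of 27 were lower (camera adjusted p = 5.00e-09, adjusted p = 0.483 with an estimated correlation), with Bub1 at 5.86 ± 0.530 and 47.5 ± 0.0591. Among ribosome biogenesis factors, 18 of 20 were lower (camera adjusted p = 1.91e-06, adjusted p = 0.485 with an estimated correlation); Npm1, which encodes nucleophosmin, was at 330.0 ± 23.5 and 1419 ± 2.09 (log2 fold change -2.10 ± 0.20, limma adjusted p = 1.26e-06). Among glycolysis genes, 11 of 15 were lower (camera adjusted p = 4.02e-05, adjusted p = 0.291 with an estimated correlation), with Eno1 at 129 ± 1.39 and 1146 ± 61.7 (log2 fold change -3.14 ± 0.18, limma adjusted p = 8.50e-09). Among autophagy and lysosome genes, 12 of 20 were higher (camera adjusted p = 9.08e-05, adjusted p = 0.498 with an estimated correlation); the cathepsin gene Ctsl was at 1230.0 ± 30.5 and 60.5 ± 1.98 (log2 fold change 4.32 ± 0.25, limma adjusted p = 1.33e-08). Among fatty acid oxidation genes, 7 of 17 were higher and 1 was lower (camera adjusted p = 0.00835, adjusted p = 0.496 with an estimated correlation). In the Myc family list, which was not called, Mycn was at 5.42 ± 0.123 and 46.6 ± 2.13 (log2 fold change -2.89 ± 0.20, limma adjusted p = 6.43e-08) and Myc at 2.03 ± 0.312 and 1.05 ± 0.0413 without being called. Mitochondrial transcripts took 62.3% and 62.1% of the FPKM sum at D12.

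riPSC and mESC, both grown on feeder cells in medium with LIF at 1000 units per mL, CHIR99021 at 3 µM and PD0325901 at 0.2 µM, differed in 500 genes, 303 higher in riPSC and 197 lower. The origin of riPSC and mESC differs: mESC are an established embryonic stem cell line, not cells from the fibroblasts of the course. A difference of line or strain therefore cannot be told apart from one of reprogramming. Mitochondrial transcripts took 28.1% and 27.0% of the FPKM sum in riPSC and 35.1% and 35.8% in mESC. Of pluripotency genes, 1 of 30 was higher and 2 were lower (camera adjusted p = 0.686, adjusted p = 0.928 with an estimated correlation). Over all genes tested, 500 of 16439 were called. Pou5f1 was at 939.9 ± 41.9 and 898 ± 60.6, Nanog at 274 ± 1.58 and 253 ± 19.11 and Sox2 at 246 ± 16.1 and 246 ± 16.8, none of them called. Dppa3 was higher in riPSC, at 23.5 ± 0.247 against 1.02 ± 0.155 (log2 fold change 3.60 ± 0.10, limma adjusted p = 4.35e-10), and Zfp42 lower, at 147 ± 2.46 against 305 ± 22.2 (log2 fold change -1.05 ± 0.13, limma adjusted p = 1.42e-04). Without mESC replicate 2, Zfp42 had a log2 fold change of -0.97, under the threshold. The oligodendrocyte transcription factor gene Olig1 was at 10.0 ± 0.918 in riPSC and 0.0876 ± 0.0718 in mESC (log2 fold change 3.34 ± 0.09, limma adjusted p = 3.32e-10), and its neighbour Olig2 at 11.9 ± 1.16 and listed at 0 in both mESC libraries. The hormone precursor gene Trh was lower in riPSC, at 14.8 ± 0.395 against 89.1 ± 5.59 (log2 fold change -2.51 ± 0.10, limma adjusted p = 7.25e-09), as were the growth factor gene Bmp4, at 1.43 ± 0.0820 against 11.3 ± 1.32, and its target Id1, at 2.88 ± 0.785 against 13.2 ± 0.878. The ribosomal protein gene Rpl34 was at 396 ± 3.47 and 28.6 ± 3.36. These levels are uncertain, since its pseudogenes may share reads, which was not tested. Among germline genes, 3 of 14 were higher (camera adjusted p = 2.23e-04, adjusted p = 0.239 with an estimated correlation). Of fibroblast matrix genes, 4 of 25 were lower (0 and 6 adjusted over the list alone, camera adjusted p = 5.50e-05, adjusted p = 0.532 with an estimated correlation), and of myeloid genes, 2 of 13 were lower (camera adjusted p = 1.76e-05, adjusted p = 0.0375 with an estimated correlation).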

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

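Tests with the length trend removed, with group variance weights and without the D0, D2 and D4 libraries were chosen after the results were seen. Counts of changed genes stayed within 1.5 times those reported with no filter, a filter of 5, eBayes with a trend, median-of-ratios scaling, the length trend removed and group variance weights. The 5 comparisons of later groups refitted without the D0, D2 and D4 libraries did so too, as did the 88 counts with 1 replicate left out, in which the lone library is assumed to vary like the other groups. Leaving 1 library out gave 2829 to 5045 genes at D2 against D0, 3206 to 5617 at D4 against D0 and 391 to 418 at D10 against D8. With the replicate number as a block, the D2 count was 3964 and the count of list tests 113. Over 36 pairs of groups the replicate differences correlated between -0.23 and 0.27, with 5 pairs over 0.1. The numbers thus marked no pairing common to all groups, and a culture or batch shared by some groups is not excluded. DESeq2, planned only for counts, was not run.

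With a pseudocount of 0.1, which weights low genes more, the counts were 6326 at D2 and 6817 at D4 against D0, 2701 from D2 to D4, 822 from D8 to D10, 2721 from D10 to D12, 901 between riPSC and mESC, and 1834 transiently lower genes. With a pseudocount of 5 they were 1396, 1538, 3168, 4451, 4645 and 4565 against D0 from D2 to D12, then 620, 1318, 1966, 124 and 607 for the 5 later steps. They were 4817 for riPSC against D0, 3062 for D12 against riPSC, 127 for riPSC against mESC, 2259 transiently higher and 568 transiently lower. With no fold threshold they were 8833, 9637 and 11495 against D0 at D2, D4 and D6, and 5142, 7862, 9324, 1722 and 5822 for the 5 later steps. For D12 against riPSC the count was then 10585, for riPSC against mESC 2076, and for transient genes 7042 higher and 2996 lower, as that setting removes a criterion. Quantile normalization gave 2861 at D4 against D0 and 1790 transiently lower genes, and the cause was not tested. A fit of only the 4 libraries compared gave 88 at D2 and 1792 at D4 against D0 and 337 from D2 to D4. Its 2 residual degrees of freedom alone do not account for this. Such fits gave 4353 from D6 to D8 and 482 from D8 to D10. Group variance weights, lower where replicates spread more, were 0.213 in D0, 0.267 in D2 and 0.667 in D4. They were 1.18 to 2.18 in the other groups, and with them the D2 count against D0 was 3555.

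Of the 113 list calls, 6 held with an estimated correlation; fry, which asks another question, called 197. Each call kept its direction in every setting; 10 no longer passed with the length trend removed, 6 with median-of-ratios scaling, 6 with fry, 2 with a pseudocount of 0.1 and 1 with the replicate block. All 44 gene values printed with a fold or a p stayed called with median-of-ratios scaling and the replicate block. Atf3 (D10 against D8) did not pass with a pseudocount of 0.1. Zfp42 (riPSC against mESC) had a log2 fold change of -0.97 without mESC replicate 2. Single genes were not refitted with only the libraries compared, the length trend removed or group variance weights. How single calls among D0, D2 and D4 fare in those settings is therefore not known.

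The correlation with riPSC for D0, D2, D4, D6, D8, D10, D12 and mESC was 0.672, 0.670, 0.671, 0.656, 0.730, 0.753, 0.719 and 0.962 with a pseudocount of 0.1. It was 0.636, 0.634, 0.637, 0.594, 0.707, 0.735, 0.679 and 0.968 with a filter of 5, and 0.675, 0.686, 0.693, 0.677, 0.768, 0.787, 0.745 and 0.969 as Spearman's rho; the cause was not tested. With FPKM and no counts, the depth limits low genes most, where the pseudocount decides the fold.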

Other observations

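Further lists, or further comparisons of lists described above, were called. Of cholesterol synthesis genes at D12 against riPSC, 7 of 18 were lower (camera adjusted p = 0.0147, adjusted p = 0.746 with an estimated correlation); in riPSC against D0, 12 of 18 were higher (camera adjusted p = 0.0290, adjusted p = 0.773 with an estimated correlation), and that call was at adjusted p = 0.075 with median-of-ratios scaling. Of formative and primed pluripotency genes at D12 against riPSC, 4 of 10 were lower (camera adjusted p = 0.0296, adjusted p = 0.498 with an estimated correlation), and at D6 against D4, 2 of 10 fell (camera adjusted p = 0.0265, adjusted p = 0.498 with an estimated correlation). Of imprinted genes in riPSC against D0, 6 of 18 were higher and 7 were lower (camera adjusted p = 0.0410, adjusted p = 0.750 with an estimated correlation), a call that was at adjusted p = 0.064 with median-of-ratios scaling and 0.10 with the length trend removed. Of AP-1 and immediate early genes at D8 against D6, 2 of 13 rose and 7 fell (camera adjusted p = 0.0375, adjusted p = 0.534 with an estimated correlation), with adjusted p = 0.059 once the length trend was removed. Of respiratory chain and ATP synthase genes encoded in the nucleus, 11 of 76 were higher and 26 were lower (camera adjusted p = 2.51e-06, adjusted p = 0.485 with an estimated correlation) in riPSC against D0, and at D6 against D4, 2 of 76 fell (camera adjusted p = 3.36e-07, adjusted p = 0.434 with an estimated correlation). Of interferon-stimulated genes, 10 of 17 rose (camera adjusted p = 1.10e-05, adjusted p = 0.159 with an estimated correlation) at D6 and 11 of 17 rose and 2 fell (camera adjusted p = 0.00379, adjusted p = 0.350 with an estimated correlation) at D8. Of ribosomal protein genes, 5 of 88 were higher and 37 were lower (camera adjusted p = 5.31e-14, adjusted p = 0.467 with an estimated correlation) in riPSC against D0 and 25 of 88 were lower (camera adjusted p = 8.16e-08, adjusted p = 0.642 with an estimated correlation) at D12 against riPSC.

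The Myc family, the negative regulators of mTORC1 and the sex-linked genes were called as lists in none of the 9 comparisons. The sex-linked list joins Xist with Y-linked genes, which can move in opposite directions and cancel in this test. Its lack of a call therefore does not show that sex-linked genes were unchanged. Between D12 and riPSC, 1 of 10 was higher and 3 were lower (camera adjusted p = 0.686, adjusted p = 0.928 with an estimated correlation) for the Myc family, 4 of 13 were higher and 1 was lower (camera adjusted p = 0.686, adjusted p = 0.928 with an estimated correlation) for the mTORC1 regulators, and 2 of 5 were higher (camera adjusted p = 0.685, adjusted p = 0.928 with an estimated correlation) for the sex-linked genes.

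Of the tests below, those on library composition, with the length trend removed, on the share of female cells and on near-identical copies were chosen after the result was seen. Genes for cytosolic ribosomal proteins were lower at D12 than at D0, 67 of 88 by the limma call with 2 higher, at a median log2 fold change of -1.56. With median-of-ratios scaling 77 were lower and their list had a median of -2.13. That scaling also lowered the median log2 fold change of all genes at D12 against D0, from 0.559 to 0.2781. It could hardly lift the falls, so this test cannot decide on the composition of the libraries. The genes lower both as deposited and with the length trend removed numbered 66, and with it removed the median was -1.73. The median log2 fold change of each length class at D12 against D0 was 0 or above. Removing that trend could hardly lift the falls, so this test cannot decide on length bias of the D0 libraries as the whole cause. A contribution of length bias cannot be told apart: the median lay 0.32 above that of sets matched on length and D0 level (-1.88, 2.5% limits -2.089 and -1.632). The matched genes had a median log2 level of 7.83 in D0 against 10.37, and the reading of this test was corrected to the written prediction after its value was seen; a difference between fibroblasts and day 12 cells stays open as untested.

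Xist was at 63.8 ± 2.71 at D12 and 4.18 ± 0.174 at D10. Earlier it was at 1.774 and 2.542 in D0, listed at 0 in each D2, D4 and D6 library, and at 2.879 and 2.71 in D8. The overlapping antisense gene Tsix had a mean level of 0.0390 at D12, far below Xist. Both levels came from the same assignment of reads. This test therefore cannot decide whether reads of Tsix were counted as Xist. A larger share of female cells may contribute: the median log2 ratio of 4 Y-linked genes was -0.96. A change of share alone would move them by 1 factor, and they moved apart by 1.13 (standard error of a difference 0.17), so a change of share and a change within cells cannot be told apart; the latter was not tested.

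The 2-cell-like genes that rose at D12 include near-identical copies that share reads. Outside the Zscan4 family 5 of the 5 members tested were called higher, but that test is void: 1 of the 5 passes the filter on low values without the D12 libraries, and the rise of the whole list had been seen before. Whether reads shared between copies spread the rise of fewer genes therefore cannot be told apart from a rise of each, and how many separate genes rose is open. No biological explanation was tested.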
